A study of Mus musculus with 2 samples.

How the data were processed

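Total RNA was measured from the lungs of newborn CD-1 mice, an outbred laboratory stock, labelled male, with 1 Affymetrix array per group. Per the labels, pairs of 10-week-old parents were mated, and from 8 days after mating the drinking water held 0 ppm (control) or 200 ppm dimethylarsinic acid (DMA, an organic arsenic compound with 2 methyl groups) for 10 days. The offspring were killed on postnatal day 0, RNA was extracted with a column kit, and the RNA of 6 animals of a group was mixed for its array. The groups were taken from the sample titles. Each group has a single array of pooled RNA, so there is no spread between replicates, no p-value is possible, and the number of arrays limits the precision of every value.

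The authors deposited a table of summarised intensity per transcript cluster (called a probe here) on a linear scale, with 65956 probes per array. Per the submitters' processing notes the arrays were processed with Affymetrix Expression Console. Its version, the summary method, the scaling between arrays and any centring are not given in the sources used here, so the scale between the arrays stays unknown. The median intensity over all probes was 98.3 in the control array and 84.0 in the DMA array, and across probes, which are not independent replicates, the log2 values of both arrays had a Pearson correlation of 0.970. Of all probes, 457 had exactly equal values in both arrays and 1756 had both values identical to those of at least 1 other probe. Values identical to those of another probe mark loci that the array does not separate.

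Gene symbols came from the platform annotation supplied with the table. It gave a single symbol to 30638 probes, several symbols to 2176 and none to 33142, which are unnamed here. Symbols were updated through the Entrez identifier with a RefSeq gene table of the mouse assembly GRCm38.p6, in which 22596 of the single-symbol probes were matched; the others kept the annotation's symbol. The deposited table names no genome build, so no coordinates are given, and a chromosome is that written in the probe identifier. For 63 of the genes examined that chromosome differed from the RefSeq one, and genes with this mismatch were not chosen for naming outside the fixed rule. Probes with several symbols were not named. For the 354 genes with several probes the probe with the highest mean level stood for the gene.

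The difference of a gene was log2(intensity + 1) in the DMA array minus the same in the control array, computed on the deposited values without further scaling. It understates the difference of genes near background. For genes with 1 array below the level filter, a bound counted from the filter's intensity is given in places, a step added after seeing the data. Of 30176 named genes, the 15088 at or above the 50th percentile of mean log2 level (an intensity of about 136) were examined. In place of a test a size rule was used: a gene was counted as higher or lower when it differed by at least 1.5-fold. The difference has no replicate check. For each of 46 gene lists the median difference of the members at or above the level filter was set against the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5, which describes these arrays and not the conditions. The lists, the size rule, the level filter, the rule for named genes and the alternatives were chosen before the data were examined, except where stated.

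The genes named by rule were the 15 highest and 15 lowest genes past the 1.5-fold rule whose probes at the filter did not differ in direction, up to 4 members of each list with the largest absolute difference, Krt8, the members of the arsenic handling list and the genes of the sex check. The rule left out predicted loci, microRNA, snoRNA and snRNA genes, olfactory, vomeronasal and taste receptors and antigen receptor segments, which were counted only. It gave 196 genes. For 2 genes past the 1.5-fold rule the probes at the filter differed in direction. Other genes chosen after their values were seen are marked as such, and the list members Krt1, Krt5, Krt14, Trp63, Sprr3, Pdpn, Csf1r and Lyz2 are named outside the rule in the same way. The list of simple epithelial keratins was drawn up with knowledge that the study's publication concerns Krt8, so its direction is not independent evidence.

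Of the 46 lists, 7 had fewer than the 4 members required. These were mucous cells (3 members, median 0.27), neuroendocrine cells (1, 0.17), B cells (2, -0.07), cartilage (2, -0.39), brown fat (2, 0.08), liver (3, -1.40) and mitochondrially encoded transcripts, which had no probe named for a single gene. The remaining 39 are given in the results. A further 10 lists were drawn up after other values had been seen, and before their own members were looked at, except for Per1, Lbp and the genes that escape X inactivation. They are used in the closing section only, apart from the second squamous list, and among them a list of MHC class II genes had a single member at the filter, with a difference of -0.07.

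The procedure was tested on simulated data for the DMA minus control difference of 15088 genes, with noise as wide as the middle of the observed differences. Of 200 genes changed 1.5-fold, 98 passed the rule, a share that follows from a change equal to the threshold. Of 200 changed 2-fold 195 passed, and of 200 changed 3-fold all 200 did. Between 171 and 176 unchanged genes passed as well in each of these runs. Of 100 random lists of 12 genes, 4 stood apart with no shift, 80 with a shift of 0.2 and 100 with a shift of 0.4 on the log2 scale. The number with no shift follows from the percentile bounds. The simulated noise was symmetric, of a single width at all levels and independent between genes, unlike the data. These runs therefore check the procedure's working and do not measure how it performs on these arrays.

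The alternatives were no level filter, a filter at the 75th percentile, the mean of a gene's probes, centring each array on its median over named genes, quantile normalization of the 2 arrays, a loess correction of the difference against mean level (span 0.3), 16 in place of 1 added before log2, thresholds of 2-fold and 1.2-fold, random lists not matched on expression, and the list mean. An alternative limited to protein-coding genes with unshared values off the Y chromosome was added after seeing the data. The medians of the 2 arrays over all named genes differed by -0.17 on the log2 scale (DMA minus control), while the median difference of the genes examined was 0.08. Both numbers set the reference against which single differences are to be read. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.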

Results

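The data are 2 arrays of neonatal mouse lung RNA. A control array holds the pooled RNA of 6 newborn CD-1 mice labelled male, and a DMA array holds that of 6 newborns, also labelled male, exposed before birth through dams that drank 200 ppm dimethylarsinic acid. Each array gave 65956 intensities, from which 15088 named genes at or above the level filter were examined. There are no replicates, so differences are described by their size on the log2(intensity + 1) scale, DMA minus control, and by the position of gene lists among matched random lists.

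The comparison asks which genes of the newborn lung differ in level after exposure of the dam to DMA. Keratins of stratified and simple epithelium were higher in the DMA array, among them Krt4 at 5.80-fold, Krt13 at 3.72-fold and Krt8 at 2.37-fold. Genes of alveolar type 1 cells were also higher as a group. By list median, genes of DNA replication, macrophages, neutrophils, club cells and ciliated cells lay lower than matched random lists. By list mean none of them stood apart, although the means themselves were below 0. Random lists draw on all genes examined, including the far lower loci described below, to which a mean gives more weight than a median. List means among protein-coding genes alone were not computed. A change of the level filter also removed the position apart for DNA replication, macrophages and neutrophils. All of these lists kept it among protein-coding genes with unshared values, a set chosen after seeing the data. Of the 877 genes counted as lower, 728 were predicted loci, small RNA genes, receptor genes, members of multi-copy families, Y chromosome loci or genes that share their values. Xist, the RNA that coats the inactive X chromosome of female cells, was at 80.7 in the control array and 19373 in the DMA array, although both pools are labelled male.

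In all, 327 genes were at least 1.5-fold higher and 877 at least 1.5-fold lower in the DMA array, or 2.17% and 5.81% of the genes examined. Higher genes made up 27.2% of these calls on the deposited scale. They made up 59.8% after centring each array on its median (998 higher, 671 lower), 64.9% after quantile normalization (1234 higher, 667 lower) and 18.6% after loess correction (223 higher, 973 lower). The balance between higher and lower therefore rests on the scaling between the arrays, which is not stated. Among protein-coding genes with values no other probe shares and identifiers off the Y chromosome, a set chosen after seeing the data, 157 of 10815 were higher and 272 lower, and 135 of those lower were predicted loci or members of multi-copy families.

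**Figure D1:**
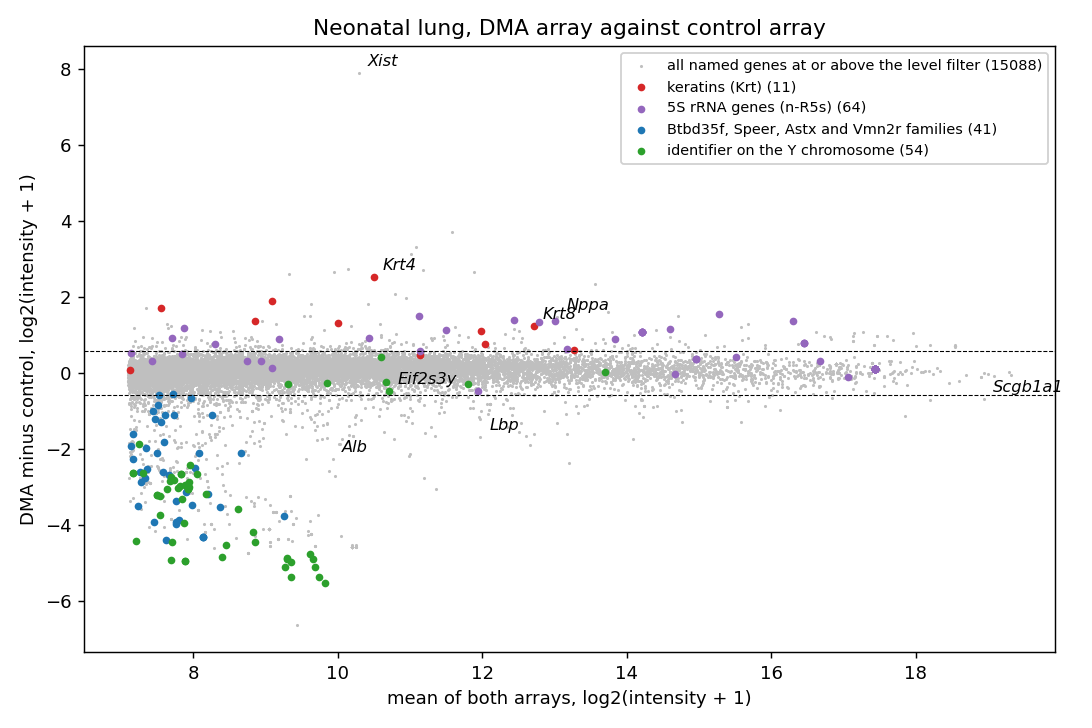
Difference between the arrays (DMA minus control, log2(intensity + 1), vertical axis) against the mean of both arrays (horizontal axis) for the 15088 genes examined, with dashed lines at 1.5-fold; each point is a gene, and coloured points are the groups in the key. The keratins lie above 0, 9 of 11 past the upper line, whereas the Btbd35f, Speer and Astx families, 16 of 18 Vmn2r genes and most genes with an identifier on the Y chromosome lie below the lower line.

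The fixed list of basal and squamous epithelium, as found in trachea and oesophagus, had 5 of 14 members at or above the level filter, and all 5 were at least 1.5-fold higher. Their median difference was 1.71, which is the value of Krt10, at percentile 100 of matched random lists. With Krt10 counted from the level filter, since its control value lay below it, the median was 1.37 (2.59-fold). Krt4 and Krt13, the keratin pair of mucosal stratified epithelium, had intensities of 599 and 281 in the control array and 3480 and 1050 in the DMA array. Krt10, a keratin of cornifying epidermis, had 103 and 338, Krt15, a basal cell keratin, 288 and 747, and Krt5, the basal cell partner of Krt14, 651 and 1622. Other members stayed near background, with Krt14 at 108 and 131, Trp63, the transcription factor of basal cells, at 68.2 and 70.2, and Sprr3 at 86.1 and 125. Krt1, which was also below the filter, had 56.7 in the control array and 247 in the DMA array. Without the level filter the median over the 13 measured members was 0.54, at percentile 100.

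A second list of 20 squamous genes, drawn up after other values had been seen, did not stand apart on the deposited scale. Its median was 0.24 at percentile 95.97 (98.965 after loess correction), with 1 of 7 members at the filter past the rule and Fat2 and Anxa8 lower, at -0.12 and -0.15. Of its members below the filter, Rhcg and Pax9 differed by -0.04 and -0.07 and Dsc3 by 0. The others were above 0, up to Krtdap at 0.62, all from values near background. A median of this list without the filter was not computed. Among the 15 highest genes, Psca, a surface protein of stratified and glandular epithelium, was 3.55-fold higher. Cnfn (cornifelin), a component of the cornified envelope, was below the level filter in the control array, at 88.9, and at 294 in the DMA array, so it was at least 2.15-fold higher. Genes chosen after their values were seen included Dsg3, a desmosomal cadherin of squamous epithelium, with a difference of 1.19 from a control value of 95.3, below the filter. Flg (filaggrin) differed by 1.12, Ppl (periplakin) by 0.98 and Tgm1, the transglutaminase that cross-links the cornified envelope, by 0.97.

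The simple epithelial keratins, a list not independent of the study's own interest, had 4 of 5 members at the filter, all at least 1.5-fold higher, with a median of 0.95 (1.93-fold) at percentile 100. Krt8 was at 4361 in the control array and 10327 in the DMA array, a difference of 1.24, and its partner Krt18 at 2750 and 5996, a difference of 1.12. Krt7 differed by 0.78 and Krt19 by 0.62. Over the alternatives Krt8 ranged from 1.13 to 1.54 and stayed past the rule, whereas Krt19 was within it after loess correction, at 0.51. Of all 11 keratin genes at the filter, 9 were at least 1.5-fold higher on the deposited scale, 10 after centring or quantile normalization and 8 after loess correction.

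Among lung cell types, alveolar type 1 cells, the thin gas exchange cells, had 10 of 11 members above 0, a median of 0.32 and percentile 99.77. Aqp5, a water channel of these cells, passed the 1.5-fold rule at 0.71, Vegfa differed by 0.53, and Clic5 and Rtkn2 by 0.42 and 0.40. Pdpn, another type 1 marker, was the exception at -0.16, and turned to 0.0083 after centring. Alveolar type 2 cells, which make surfactant, had a median of 0.06 at percentile 30.2 with 0 of 13 members past the rule. In that list Sftpd differed by 0.49, Napsa by 0.42 and Cxcl15 by -0.32.

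Of the airway lists, those of ciliated and club cells lay on the low side, unlike the basal and squamous list above. The mucous cell list, too small to be placed among random lists, had 3 of 3 members above 0. All 14 ciliated cell genes at the filter were below the median of all genes examined on the deposited scale, and after quantile normalization and loess correction. Centring cannot change this. The list median was -0.17 at percentile 0.88 and the list mean -0.25 at percentile 20.5. Dynlrb2, a dynein light chain, differed by -0.69 and Cfap126 by -0.59, both past the rule on the deposited scale and within it after centring. Cfap126 was below the level filter in the DMA array, and counted from that filter its difference was -0.56, within the rule. Dnali1 differed by -0.42. Club cells, the secretory cells of the bronchioles, had a median of -0.13 at percentile 0.70, which turned to 0.04 after centring while the percentile stayed at 0.70. By list mean the percentile was 4.53. Their main product Scgb1a1 was at 639493 in the control array and 399388 in the DMA array, a difference of -0.68 that centring brought within the rule. Scgb3a2 differed the other way, by 0.42.

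**Figure D2:**
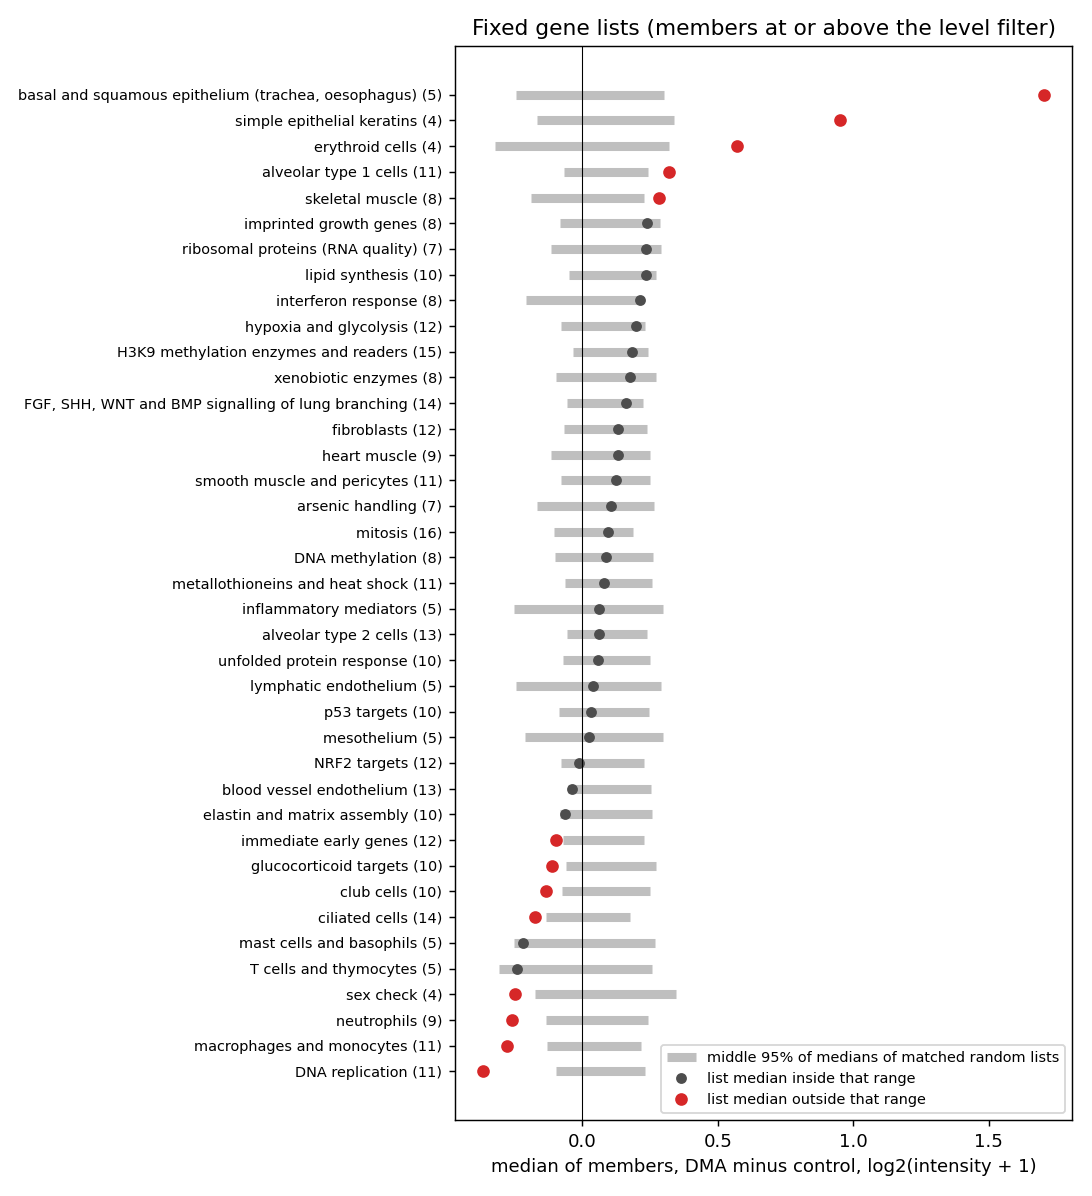
Median difference (DMA minus control, log2(intensity + 1), horizontal axis) of each of the 39 fixed lists with at least 4 members at the level filter, with the number of members in brackets; grey bars are the middle 95% of medians of 10000 matched random lists. The basal and squamous list at 1.71, the simple keratins at 0.95 and erythroid cells at 0.57 lie to the right of their bars, and DNA replication at -0.37 lies farthest to the left.

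Blood cell lists differed from each other. Erythroid genes had 4 of 17 members at the filter and a median of 0.57 at percentile 99.97. Of the others, 8 had no probe named for them alone, 5 of them haemoglobin genes, and 5 were measured below the filter, with differences from -0.16 to 0.056. Without the level filter their median was 0.056 at percentile 84.7, no longer apart. Alas2, the first enzyme of haem synthesis in red cells, was 1.73-fold higher and Slc4a1, the band 3 anion exchanger, 1.60-fold higher. Macrophage and monocyte genes had a median of -0.28 at percentile 0.14, with 8 of 11 members below the median of all genes. That position was lost by list mean, at percentile 22.1, and with the 75th percentile filter, at 9.66. Cd68 (-0.63) passed the rule, Ly6c2 (-0.58) and Marco (-0.52) did not, and Csf1r (0.19) and Lyz2 (0.23) differed the other way. Neutrophil genes had a median of -0.26 at percentile 0.23, with 9 of 9 members below the median of all genes, but did not stand apart by list mean (-0.34) or without the level filter (-0.12, percentile 5.80). Ngp differed by -0.79, Retnlg by -0.68 and S100a8 by -0.62. After centring, Cd68, S100a8 and Retnlg were within the rule. T cell genes (5 members, -0.24, percentile 4.69) and mast cell genes (5, -0.22, percentile 3.64) did not stand apart.

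Genes of DNA replication had a median of -0.37 at percentile 0.04, the lowest percentile of any list. On the deposited scale, and after quantile normalization and loess correction, 11 of 11 members were below the median of all genes. By list mean the percentile was 8.35, and with the 75th percentile filter it was 5.02, so the list did not stand apart in either. The helicase subunits Mcm3, Mcm5 and Mcm4 differed by -0.71, -0.55 and -0.43, and Rrm2, a subunit of ribonucleotide reductase, by -0.60. Mcm3 and Rrm2 passed the rule on the deposited scale and not after centring. The list of mitosis genes, by contrast, had a median of 0.09 at percentile 71.8 and 0 of 16 members past the rule, with Cdc20 at 0.44 and Ccnb2 at -0.34.

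Several lists that touch arsenic exposure did not stand apart by their medians. In the list of arsenic handling, with 7 members and a median of 0.11 at percentile 60.9 (98.2 by list mean), Gsto1, a glutathione transferase that reduces methylated arsenicals, was 1.82-fold higher. Slc2a1, a glucose transporter, was 1.73-fold higher. As3mt, the arsenic methyltransferase, differed by 0.12, Abcc4 by 0.11, N6amt1 by 0.08, Abcc1 by -0.02 and Pnp by -0.07, and the last 3 of these changed sign under another scaling. Gsto2, Aqp3, Aqp7, Aqp9 and Abcc2 were below the level filter by their mean over both arrays, with DMA intensities of 54.1, 158, 85.4, 43.3 and 36.2. Aqp3 alone of these was above the filter in the DMA array. Its control intensity was 110, a difference of 0.51 (0.68 after centring, past the rule). NRF2 targets, the antioxidant response, had a median of -0.01 at percentile 12.1, with Gclc at 0.48. Gstm1 at -0.39 and Hmox1 at -0.13 turned to 0.031 after quantile normalization. Metallothioneins and heat shock genes had a median of 0.08 at percentile 37.2. Both metallothioneins were lower, Mt1 by a difference of -0.61 and Mt2 by -0.59, and centring brought both within the rule. p53 targets had a median of 0.03 at percentile 26.4, with Perp at 0.61 (0.49 after loess correction) and Cdkn1a at -0.34, which turned to 0.084 after quantile normalization. The enzymes and readers of histone H3 lysine 9 methylation (H3K9 in the key) had a median of 0.18 at percentile 84.4 and 0 of 15 members past the rule, with Phf8 at 0.33 and Ehmt1 at 0.29. DNA methylation genes had a median of 0.09 at percentile 47.5, with Uhrf1 at -0.41.

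Response lists on the low side were immediate early genes, with a median of -0.09 at percentile 1.49, and glucocorticoid targets, with -0.11 at percentile 0.77. Both medians were above 0 after centring, at 0.08 and 0.06, with the same percentiles. By list mean neither stood apart, at percentiles 23.7 and 15.7. Immediate early genes also did not stand apart without the level filter (median 5.03e-05, percentile 20.7), with the 75th percentile filter (7.74) or with unmatched random lists (2.53). Nr4a1 differed by -0.90, Jun by 0.45 and Ier3 by 0.54. Per1, a clock gene that glucocorticoids also regulate, differed by -1.02, Lcn2 by -0.76 and Pdk4 by -0.60 (-0.42 after centring). Fkbp5, another glucocorticoid target, differed the other way, by 0.31, and 3 of 10 members of that list were above 0. Interferon response genes had a median of 0.21 at percentile 97.4, just within the range of random lists, with Rsad2 at 1.36 and Ifit1 at 0.71 (within the rule, at 0.53, when counted from the filter) but Bst2 at -0.70 (-0.53 after centring) and Ifit3 at -0.55. Hypoxia and glycolysis genes had a median of 0.20 at percentile 92.3, with Adm (adrenomedullin) 2.58-fold higher. Inflammatory mediators had a median of 0.06 at percentile 47.5, and the unfolded protein response one of 0.06 at percentile 27.4.

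Markers of skeletal muscle, heart muscle and liver gave differing results, and the liver list had too few members to be placed among random lists. Skeletal muscle genes stood apart, with a median of 0.28 and percentile 99.51. Of the 8 members, 8 were above 0, 7 above the median of all genes and 1 past the rule. Among them Myh3 differed by 0.76, Myh8 by 0.45 and Tnnt3 by 0.42. Heart muscle genes did not stand apart, with a median of 0.13 at percentile 63.6. Nppa, the atrial natriuretic peptide precursor, was 2.79-fold higher and Myh6 1.55-fold higher (within the rule after loess correction, at 0.52), whereas Myl7 differed by -0.35. Of 3 liver genes at the filter, Alb (albumin) was at 2135 and 444, a difference of -2.26, Ahsg differed by -1.40 and Trf by 0.69. Below the filter, Afp, Fgb, Apoa1, Apoa2 and Ttr were also lower, so that 7 of 8 measured liver genes were below 0.

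The other lists did not stand apart. Their medians were -0.04 for blood vessel endothelium (percentile 3.56), 0.04 for lymphatic endothelium (38.0), 0.13 for fibroblasts (67.3), 0.13 for smooth muscle and pericytes (64.3) and 0.02 for mesothelium (32.1). They were -0.07 for elastin and matrix assembly (3.89), 0.24 for lipid synthesis (92.9), 0.18 for xenobiotic enzymes (79.5), 0.24 for imprinted growth genes (92.6) and 0.16 for the signalling genes of lung branching (82.2). Ribosomal protein genes, a sign of RNA quality, had a median of 0.24 (89.7). Members of these lists past the rule were Dcn at 0.60 and Col4a1 at 0.60, both within it after loess correction, at 0.48 and 0.50. Of 39 lists, 13 stood apart, 5 on the high side and 8 on the low side, where about 1.95 would do so by chance if their genes were unrelated. Genes of a list can move together and some lists share genes, so this number is no measure of an excess. The 13 also include the simple keratins, which are not independent of the study's interest, and the sex check.

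**Figure D3:**
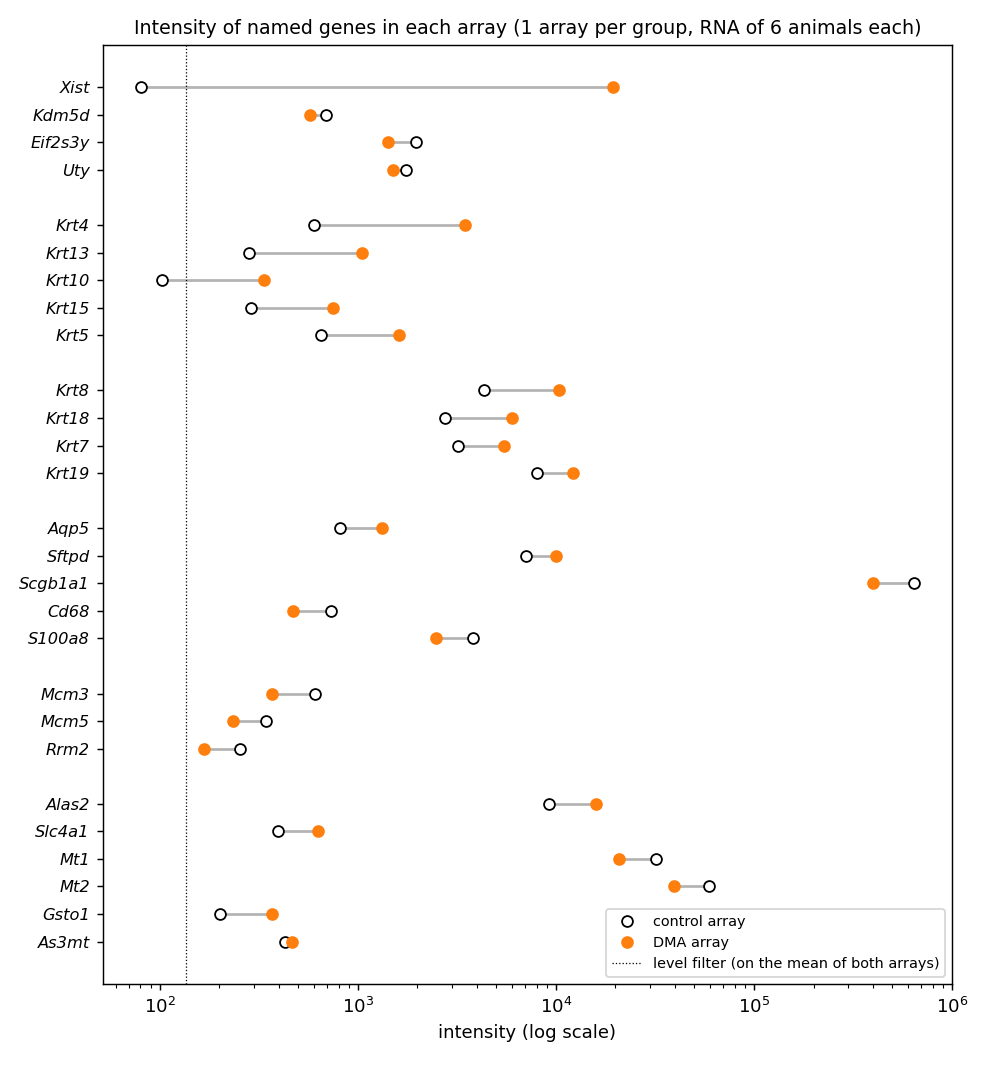
Intensity on a log axis (horizontal) of named genes in the control array (open circles) and the DMA array (filled circles), each circle being a single array of 6 pooled animals; the dotted line marks the level filter at 136. Xist lies at 80.7 and 19373, Krt4 at 599 and 3480 and Krt8 at 4361 and 10327, whereas Scgb1a1 and Mcm3 lie lower in the DMA array on the deposited scale.

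The sex check gave differing answers in the DMA array. Xist was at 80.7 in the control array, below the level filter, and at least 141-fold higher in the DMA array counted from that filter. The single-copy Y chromosome genes were well above the level filter in both arrays, with Kdm5d at 696 and 575, Eif2s3y at 1966 and 1414 and Uty at 1760 and 1512, differences of -0.27, -0.48 and -0.22. Ddx3y has no probe named for it alone. The list as a whole had a median of -0.25 at percentile 1.27, since 3 of its 4 members are Y genes.

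The lowest genes of the rule were mostly members of multi-copy families, and 5 of the 15 share their values with other probes. In the DMA array 13 of the 15 lowest named genes lay below the level filter, so the sizes of these differences depend on background. Astx3, on the X chromosome, was at 897 and 42.2, and Astx1a, Astx1b and Astx1c shared a single pair of values with a difference of -4.31. All 13 Btbd35f genes were lower, with a median of -3.03, as were all 5 Speer genes, with a median of -3.46, and 16 of 18 Vmn2r genes, which encode vomeronasal receptors, with a median of -1.44. Csprs on chromosome 1 differed by -3.88. Of 54 genes with an identifier on the Y chromosome 47 were lower, with a median of -3.11. Counted from the level filter, the medians were -2.17 for Btbd35f, -2.69 for Speer, -1.08 for Vmn2r and -2.29 for the Y chromosome. The medians of the Astx, Btbd35f, Speer and Vmn2r families were below 0 under every scaling. Chromosomes 7 and 14 held 216 and 113 of the genes counted as lower.

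Small RNA classes contributed many calls. Of 506 snoRNA genes 180 were lower and 40 higher, and of 238 microRNA genes 83 were lower and 4 higher. After centring these were 163 and 62 snoRNA genes and 73 and 19 microRNA genes. Among snoRNA genes with a Snord or Snora number the calls were mostly higher, with 9 of 42 Snord genes higher and 0 lower and 7 of 17 Snora genes higher and 1 lower. After centring 14 Snord genes were higher and 0 lower, and after loess correction 5 and 1. For Snora genes these were 7 and 0 after centring and 6 and 1 after loess correction. Most Snord genes stayed within the rule. Of 64 5S ribosomal RNA genes and their copies 24 were higher and 0 lower, with n-R5s151 at 23364 and 68279, but 37 of these genes share their values with other probes.

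Protein-coding genes with unshared values, outside the families above, were also chosen after their values were seen. The lower ones included Zfp640, a zinc finger gene, with a difference of -2.26. Lbp, the lipopolysaccharide-binding protein, was at 7175 and 2248, a difference of -1.67. Phex differed by -1.56, the fatty acid transporter Slc27a6 by -1.42, the glutathione transferase Gstp1 by -1.32 and the phospholipase Pla2g1b by -1.29. The chemokines Cxcl17 and Ccl11 differed by -1.07 and -1.04. Higher genes chosen in the same way included the proton pump subunit Atp6v0a4 (1.25), the paraoxonase Pon1 (1.22), the amino acid transporter Slc6a14 (1.02) and the cytokine Il33 (0.81).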

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

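Probes that carry no single gene symbol took no part in the comparison of genes. At or above the same level filter, 359 of 10196 probes without a symbol and 16 of 1246 probes with several symbols were at least 1.5-fold higher in the DMA array than in the control array, which is why they were set apart for a closer look. These were 3.52% and 1.28% of the probes, against 2.17% of the named genes examined. Lower probes departed further, with 2226 of those without a symbol (21.8%) and 315 of those with several (25.3%), against 5.81% of the named genes. No biological explanation was tested for these probes, since they are not named here.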

How the results depend on the processing

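With a single array per group no library could be left out, and no paired analysis was possible because each group has 1 array of pooled RNA. The alternative limited to protein-coding genes was chosen after seeing the data, and the cause of a shift was not tested unless the alternative's own construction shows it. The 327 higher genes became 998 after centring and 1234 after quantile normalization, and all 327 were among them both times. Centring raises all differences by the same amount, so it could not remove any of them. They became 75 at 2-fold, 2927 at 1.2-fold and 157 among protein-coding genes. The 877 lower genes became 2417 without the level filter, 267 with the filter at the 75th percentile, 527 at 2-fold, 1964 at 1.2-fold and 272 among protein-coding genes. Of 20 recomputed counts the other 10 stayed within 1.5 times. The 13 lists that stood apart did so on the same side in 108 of 124 recomputed cases. All of them did so after quantile normalization, loess correction, 16 added before log2 or the mean of probes. The same held after centring, but centring shifts a list and its random lists alike, so those cases could not have differed. Without the level filter the medians of neutrophils (-0.12) and erythroid cells (0.056) no longer stood apart, and that of immediate early genes went to 5.03e-05; members near background then enter. With the 75th percentile filter, which leaves fewer members, macrophages (-0.068), DNA replication (-0.12) and immediate early genes (-0.026) did not stand apart, and with unmatched random lists immediate early genes (-0.095) and the sex check (-0.25) did not. By list means, club cells (-0.16), ciliated cells (-0.25), macrophages (-0.21), neutrophils (-0.34), DNA replication (-0.35), immediate early genes (-0.052) and glucocorticoid targets (-0.21) did not stand apart, and the sex check turned to 1.73 because Xist enters the mean. The means of random lists likewise take in the far lower multi-copy loci. Among the other 26 lists, a position apart was gained by lung branching signals without the filter (0.22). It was gained by T cells (-0.24) and mast cells (-0.22) with unmatched random lists and among protein-coding genes, and there also by endothelium (-0.038) and matrix assembly (-0.065). By list means, heart muscle (0.29), arsenic handling (0.27) and hypoxia (0.32) gained it. Of the named genes past the 1.5-fold rule 0 changed sign, while 16 within it did. Of 1372 recomputed differences 38 dropped below the rule and 73 newly passed it. Signal over background limits all of this, since 15088 named genes lay below the level filter and were not examined.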

Other observations

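The gene lists of this paragraph were drawn up after other values had been seen, among them those of Per1 and Lbp, which are members of the clock and complement lists. Genes of lung fluid clearance and ion transport had a median difference of 0.28 at percentile 97.7 of matched random lists, with 0 of 7 members past the 1.5-fold rule. Slc12a2, a chloride cotransporter, differed by 0.52, the sodium pump subunit Atp1b1 by 0.51 and the sodium channel subunits Scnn1a and Scnn1g by 0.44 and 0.28, whereas Cftr differed by -0.17 and turned to 0.0013 after centring. Clock genes of the evening phase had a median of -0.18 at percentile 2.02, with Per1 at -1.02 and Nr1d1 at -0.90 past the rule. That position was lost under quantile normalization, at percentile 3.71, and under loess correction, at 4.37, and quantile normalization also turned the median to 0.01. Clock genes of the morning phase had a median of 0.26 at percentile 92.8, with Arntl at 0.65 and Cry1 at 0.49, and did not stand apart. Complement and acute phase genes had a median of -0.27 at percentile 2.27, with Lbp at -1.67 and Saa1 at -0.50.

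Of the tests that follow, those on Xist and on a smaller number of Y chromosomes were chosen after the results were seen. The number of loci required for the genomic DNA test and the leaving out of predicted loci from the X chromosome test were also not part of what was written down beforehand.

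Xist was near background in the control array and at 19373 in the DMA array. A DMA pool of female animals only is argued against by the Y genes, the lowest of which was at 575 against a level filter of 136. Xist switched on in male cells would silence their only X chromosome, but X-linked protein-coding genes differed from autosomal ones by a median of -0.00075, with a bootstrap interval over genes from -0.04 to 0.02. RNA of female animals as part of the DMA pool, as from a mislabelled animal, may contribute. Kdm5d, Eif2s3y and Uty were at 82.7%, 71.9% and 85.9% of their control intensity on the deposited scale. Their differences were -0.10, -0.30 and -0.05 after centring and -0.38, -0.60 and -0.34 after loess correction, so the size of this drop rests on the scaling. Further, 7 of 7 genes that escape X inactivation were above 0, and 6 of the 7 were above the median of all genes. Their list median was at percentile 95.92 of random lists, just short of the bound for standing apart. That percentile was 99.8 after quantile normalization and 98.3 after loess correction, so this explanation stays open, as does an effect of DMA on Xist that leaves the X chromosome unsilenced, which was not tested.

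Several multi-copy families were far lower in the DMA array, on the Y chromosome and elsewhere, whereas of 64 5S ribosomal RNA genes and their copies 24 were higher and 0 lower. Fewer Y chromosomes in that pool, as the cause of this loss, are argued against by the single-copy Y genes. The lowest of them differed by -0.48, while the other 51 Y genes had a median of -2.32 even when counted from the level filter. The 23 autosomal Speer and Vmn2r genes, with a median of -1.18 counted in the same way, argue against it as well. The single-copy Y genes were themselves lower on the deposited scale, so a somewhat smaller number of Y chromosomes is not excluded. Spermatid RNA in the control pool is argued against by 12 spermatid genes, which had a median of -0.094 and all lay below the level filter, the brightest at 129 in the control array. Genomic DNA in the control RNA could give a loss that grows with copy number, and among coding and pseudogene loci off the Y chromosome the median was 0.09 for loci with unshared values, -0.14 for values shared by 2 probes, -0.84 for 3 to 4 probes and -2.63 for 5 or more (-2.09 counted from the level filter). The gap of -2.49 between the last class and that of 2 probes went the predicted way but rests on 3 loci, so genomic DNA and a lower transcription of such loci in exposed lungs cannot be told apart.

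Keratins were higher in the DMA array, while a second squamous list did not stand apart, at percentile 95.97 with 1 of 7 members past the rule. Scaling between the arrays is argued against for Krt8, whose lowest difference under the other scalings was 1.13, after loess correction. Centring and quantile normalization raised Krt8, to 1.41 and 1.54, so they put it to no test. Krt19 was within the rule after loess correction, at 0.51, while 8 of 11 keratins stayed past it. A larger share of all epithelium, as the whole cause, is argued against by 10 general epithelial genes on the deposited scale. Their median of 0.26, and 0.14 after loess correction, lay under the bound set beforehand. After centring (0.44) and quantile normalization (0.40) it lay between the bounds, so the answer rests on the scaling. Under each scaling it was below the median of the simple keratins, at 0.95, 1.12 after centring, 1.16 after quantile normalization and 0.83 after loess correction. All 10 were above 0, and 9 of them were above the median of all genes on the deposited scale. The list was at percentile 97.51, with a highest value of 0.49. After quantile normalization and loess correction the highest values were 0.86 and 0.38, and the list did not stand apart, at percentiles 92.2 and 96.0. A smaller contribution of this kind therefore stays open. Squamous epithelium of neighbouring organs stays open, since the second squamous list had a median of 0.24, between the bounds set beforehand, and other neighbouring tissues went both ways, with skeletal muscle at 0.28 (percentile 99.51), heart muscle at 0.13 (percentile 63.6) and 7 of 8 liver genes below 0. For Krt8 and Krt18 an alveolar transitional state is likewise open, since the median of 6 other genes of that state, 0.28, lay between the bounds set beforehand. That list did not stand apart, at percentile 96.4 with 0 of 6 members past the rule. Of its members 4 were above 0, while Nupr1 and Plaur both differed by -0.28. An effect of DMA on the lung epithelium was not tested apart from these.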
